A study of Mus musculus with 4 samples.

How the data were processed

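Nuclei from the deep cerebellar nuclei of C57BL/6J mice were profiled by single-nucleus RNA sequencing on the 10x Genomics platform, per the labels' protocols. The tissue was micro-dissected from vibratome slices, and no sorting of nuclei is recorded in the labels. Per the labels, 2 libraries came from the Ucn3-Cre line (replicate 1: female, 3 months, iodixanol gradient; replicate 2: male, 3 months, sucrose cushion) and 2 from the vGluT2-Cre line (replicate 1: male, 2 months, sucrose cushion; replicate 2: female, 2.5 months, sucrose cushion). Both lines were crossed with Ai32, a strain that makes channelrhodopsin fused to EYFP after Cre recombination. Age therefore differed between the lines, and 1 library was extracted in another way than the other 3. The library was the unit of replication throughout.

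The authors used Cell Ranger 3.1.0 and Seurat 3.2 with the mm10 genome build, per the submitters' processing notes. Per the file headers, the deposited tables list 15632 genes by symbol for each nucleus of each library, and a further table holds 480 nuclei that the submitters named vglut2, with values that differ from those of the library tables by at most 0. The deposited values are expected counts: 97.2 to 98.8% of the values above 0 in each library lie within 0.5 below a whole number, as after subtraction of an estimated background. The step that made them is not named in the sources used here. After this step 92.8 to 95.7% of the counts, rounded up, remained per library. The values were not scaled to depth. Every deposited nucleus had at least 1000.1 corrected counts and 611 genes, and at most 4.99% of counts from mitochondrial transcripts. Positions are those of GENCODE vM21 on GRCm38, the same build as mm10.

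Nuclei with at least 200 genes and at most 5% mitochondrial counts were kept, which removed none. Scrublet, as implemented in scanpy 1.11.5, marked 49 of 21494 nuclei (0.228%) with its automatic threshold. By the fixed rule for shares under 0.5%, the nuclei with the highest scores were removed instead, 0.8% per 1000 nuclei of a library, 947 in total. The remaining 20547 nuclei were scaled to 10000 counts and log-transformed. Then 2000 variable genes were chosen with the library as batch, without members of the fixed gene lists. With them, 30 principal components, 15 neighbours and Leiden resolution 1 gave 20 clusters, with no integration of libraries. A cluster took the name of the class whose markers had the highest mean scaled expression, if its mean score was at least 0.3, at least 3 markers were detected in 10% of its nuclei, and the 10 leading genes held no more markers of another class. Clusters 4 and 13 stayed unnamed under this rule, as did glutamatergic sub-clusters 2, 4 and 6. Glutamatergic nuclei were clustered again (values scaled within each library, 1000 variable genes, 15 components, resolution 0.5).

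Counts were summed per library, and per library and class, and rounded. Sums were compared with edgeR 4.0.16 (filterByExpr, TMM, quasi-likelihood test) with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The line and sex comparisons set 2 libraries against 2. Glutamatergic nuclei were compared with inhibitory neurons, and glutamatergic sub-clusters with one another by an F test, with the library as block. Classes needed at least 20 nuclei per library and sub-cluster sums at least 5 nuclei. CPM are summed counts scaled to 1e6 per sum, scaled by TMM except in levels by class. Because classes and sub-clusters were drawn from the same counts, p-values across them are too small, although the list genes took no part in clustering. Class shares were compared by a two-sided exact permutation test, which 2 libraries against 2 cannot bring below 0.333, with adjustment over 11 classes, the unnamed nuclei among them. Shares of single libraries carry 95% exact Clopper-Pearson intervals, which cover counting error only. The limit that a count of 0 allows is 3 counts.

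The 12 gene lists were those of receptors for appetite and satiation signals, neuropeptides and granins, glutamate receptors, GABA and glycine receptors, voltage-gated channels, immediate early genes, heat shock genes, mitochondrial transcripts, nuclear genes of oxidative phosphorylation, haemoglobin, hindbrain Hox and brainstem genes, and sex-linked genes. They, 16 lists of cell type markers, the tests and most of the alternatives were fixed before the data were examined. Lists were tested with camera of limma 3.58.1, with its preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. With an estimated correlation the test has only the few residual degrees of freedom of the fit, so hardly any list can pass. A call lost there is therefore not evidence against it. The preset takes list members as nearly independent, so its p-values are too small where members move together between libraries. None of the 18 hindbrain and brainstem genes was analysed here, and haemoglobin genes were too few for a list test in neurons. For the line and sex comparisons the rule for named genes took the 10 largest changes in each direction that passed the threshold without overlap of the groups, passing list members, and Slc17a6 whatever its result. For the class and sub-cluster comparisons it took up to 6 passing members per list with the largest change and the same sign in every library, and Crhr1, Lepr and Glp1r whatever their result. Other genes named in the line and sex comparisons were chosen after their values were seen.

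Ucn3, Ucn, Ucn2, Crhr2, Mc4r, Mc3r and some other list members were not analysed here. The planned comparisons of Ucn3 between classes, across sub-clusters and between nuclei with and without a Ucn3 count were therefore not run, and members of the lists were tested across sub-clusters and against all other nuclei instead. The alternatives fixed then changed the gene minimum (500), doublet removal, Leiden resolution (0.5 and 2), scaling within libraries, the glutamatergic nuclei used (those of the deposited table), size factors, the low-count filter, blocks and second terms, the sub-cluster resolution, equal depth and equal class shares. Others used DESeq2 1.42.0 or left out each library in turn. At Leiden resolution 2 the class named glutamatergic held 29 and 61 nuclei of the Ucn3-Cre replicates and 58 and 29 of the vGluT2-Cre replicates. In the main setting it held 102 and 158, and 189 and 93. Results at that resolution are therefore those of a smaller class. Alternatives chosen after seeing the data required at least 1000 genes per nucleus, left out sub-clusters 2 and 6, sub-cluster 6 or cluster 7, counted cluster 4 with the oligodendrocytes, or kept only genes with a count in each of the 4 libraries together with the sex-linked list. The last was chosen after the planned sex fit had left Xist short of the threshold. In all, 4186 of the 15632 genes were listed at 0 in at least 1 library, and 11446 were counted in every library.

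The fits were tested on simulated data, in which 100 genes were changed 2-fold and 100 others 4-fold in 1 group. Each set was raised and lowered in equal numbers. For sub-clusters the changed sub-cluster was drawn at random for each gene. Counts were drawn around each gene's mean share with the spread usual at its expression level. Spread particular to single genes and genes at 0 in whole libraries were not simulated. The percentages called therefore do not tell what share of real changes the fits would call, and the planned sex fit left Xist short of the threshold. In each fit 4 to 10 unchanged genes were called. The planned line fit of all nuclei called 12% of genes changed 2-fold and 56% of those changed 4-fold, and the fit of genes counted in every library called 58% and 99%. The sex fits called 18% and 60% as planned, and 73% and 100% with genes counted in every library. The line fit of glutamatergic nuclei called 16% and 68%, the comparison with inhibitory neurons 90% and 100%, and the sub-cluster test 45% and 86%. Work was done in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, python-igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9) and R 4.3.3.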

Results

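Gene expression was measured in single nuclei of the mouse deep cerebellar nuclei, the output structures of the cerebellum, in a series whose title concerns glutamatergic neurons of these nuclei and satiation. The Ucn3-Cre line expresses Cre under control of the urocortin 3 gene. The vGluT2-Cre line marks glutamatergic neurons that use the vesicular transporter Slc17a6. Each line gave 2 libraries. The deposited tables held 4291 and 6587 nuclei for Ucn3-Cre replicates 1 and 2, and 5642 and 4974 nuclei for vGluT2-Cre replicates 1 and 2. Corrected counts totalled 9096357 and 16219109 in the Ucn3-Cre libraries and 16412271 and 19125488 in the vGluT2-Cre libraries. The median nucleus had 1730 and 1999 counts in the Ucn3-Cre libraries and 2336 and 3206 in the vGluT2-Cre libraries. Across genes, log2 CPM of vGluT2-Cre replicate 1 had Pearson correlations of 0.963 to 0.968 with the other libraries. Those had correlations of 0.982 to 0.993 among themselves. Genes are not independent replicates.

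Glia made up most of the dissected tissue, with oligodendrocytes the most frequent class in each library and astrocytes the next. Glutamatergic cerebellar nuclear neurons were 542 of the 20547 nuclei kept, and 470 of them were also in the deposited vglut2 table. They include the 42 nuclei of sub-cluster 6, which had markers of inhibitory neurons. They made up 2.46% of nuclei in Ucn3-Cre replicate 1 (102 of 4144, 95% exact interval 2.01 to 2.98%) and 2.53% in replicate 2 (158 of 6240, 2.157 to 2.95%). In the vGluT2-Cre line they made up 3.51% in replicate 1 (189 of 5387, 3.03 to 4.03%) and 1.95% in replicate 2 (93 of 4776, 1.57 to 2.38%). The mean share was 2.50% ± 0.05 (SD, n = 2) in the Ucn3-Cre line and 2.73% ± 1.10 (SD, n = 2) in the vGluT2-Cre line. The difference of -0.23 percentage points was smaller than the spread between the vGluT2-Cre libraries (exact permutation p = 1). Inhibitory nuclear or Golgi neurons made up 4.52% ± 0.618 and 5.95% ± 2.14 (SD, n = 2 each, exact permutation p = 0.667). Oligodendrocytes made up 42.2% ± 1.77 and 48.7% ± 4.58, and astrocytes 26.2% ± 2.39 and 23.0% ± 1.15 (SD, n = 2 each, exact permutation p = 0.333 for both, the smallest this design allows). Adjusted over the 11 classes, with the unnamed nuclei as 1 of them, each p was 0.917 or more. Unnamed cluster 4, whose highest marker score was that of oligodendrocytes, is not in these shares. It made up 12.7 and 10.5% of the Ucn3-Cre libraries and 2.38 and 10.1% of the vGluT2-Cre libraries. With it, an alternative chosen after seeing the data, oligodendrocytes made up 53.8% ± 0.234 and 55.0% ± 0.901, and the difference shrank from -6.52 to -1.19 percentage points (exact permutation p = 0.333). The difference for glutamatergic nuclei turned to 0.549 percentage points without vGluT2-Cre replicate 1 and to 0.447 with at least 1000 genes per nucleus. Without sub-cluster 6, chosen after seeing the data, it was -0.11, and it came to -1.01 without vGluT2-Cre replicate 2.

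**Figure D1:**
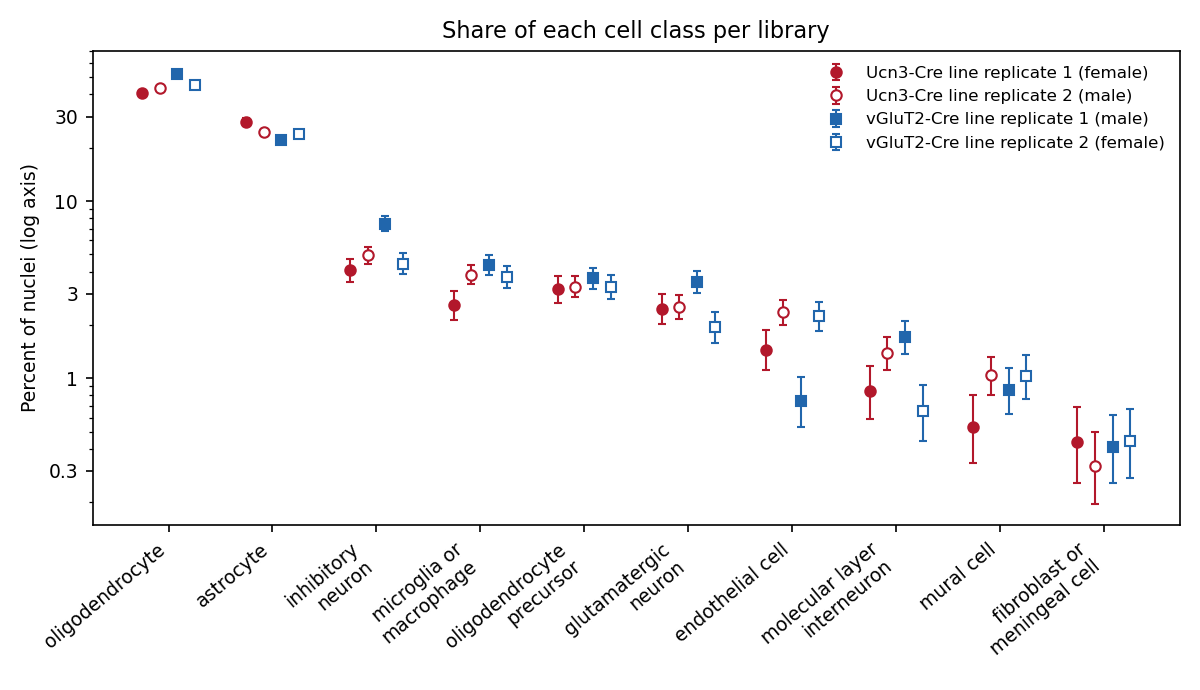
Percent of nuclei in each named class (vertical axis, log scale) for each of the 4 libraries (points), with 95% exact binomial intervals (bars). Glutamatergic neurons lie between 1.95 and 3.51% of nuclei, and their highest and lowest shares are both in the vGluT2-Cre line.

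The line comparison asks how gene expression differs between the Cre lines. The deposited tables list a gene under the symbol YFP, without its sequence, and the Ai32 reporter encodes a yellow fluorescent protein. In sums over all nuclei YFP averaged 21.0 ± 1.71 CPM in the Ucn3-Cre line and 55.9 ± 7.20 CPM in the vGluT2-Cre line (SD, n = 2 each; log2 fold change -1.42, SE 0.15; adjusted p = 0.589). Kcnab1, an auxiliary potassium channel subunit, averaged 203 ± 7.30 and 102 ± 8.83 CPM (log2 fold change 0.99, SE 0.12, adjusted p = 0.589), and the haemoglobin gene Hba-a1 55.0 ± 8.70 and 26.0 ± 5.28 CPM (log2 fold change 1.08, SE 0.21, adjusted p = 0.603; 0.49 with the same share of each class in every library). These 3 genes were chosen after their values were seen, from those past the threshold with DESeq2. Slc17a6 (ENSMUSG00000030500, GRCm38 chromosome 7, 51622006 to 51671119, plus strand) averaged 40.6 ± 18.6 and 47.4 ± 3.98 CPM (log2 fold change -0.21, SE 0.37, adjusted p = 1.00), and its sign turned without Ucn3-Cre replicate 1 (0.19; -0.79 without Ucn3-Cre replicate 2). In edgeR's quasi-likelihood test 0 of 13795 genes passed the threshold, with 478 at an unadjusted p under 0.05. DESeq2 called 238, of which 209 were listed at 0 in at least 1 library. With only genes counted in every library, an alternative chosen after seeing the data, edgeR called 0 of 11421 genes (222 at an unadjusted p under 0.05) and DESeq2 6, among them YFP, Kcnab1 and Hba-a1. In that alternative 189 genes passed without vGluT2-Cre replicate 2, and 2 (YFP and Gm42695) without vGluT2-Cre replicate 1.

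Among the gene lists, members of the haemoglobin list, which marks blood, were higher in the Ucn3-Cre line as a set in camera (median log2 fold change 0.95, adjusted p = 0.00353), with 0 of 5 genes past the threshold over all genes and 2 adjusted over the list alone. Marker sets of endothelial cells (median 0.95, adjusted p = 0.00353) and mural cells (median 0.65, adjusted p = 0.00425) were also higher as sets. So were heat shock genes (median 0.14, adjusted p = 0.0218), while GABA and glycine receptors were lower (median -0.28, adjusted p = 0.0402). With an estimated correlation none of these 5 calls held (adjusted p = 0.908 for each). Endothelial nuclei made up 0.743% of vGluT2-Cre replicate 1 and 1.45 to 2.36% of the other libraries. Unnamed cluster 13, with its highest score for endothelial markers and mural genes among its leading ones, made up 2.99 and 1.88% of the Ucn3-Cre and 0.761 and 2.81% of the vGluT2-Cre libraries. Nuclei named mural were not more frequent in the Ucn3-Cre line (0.531 and 1.04% against 0.854 and 1.03%). The other lists did not pass (adjusted p = 0.0586 or more), and 0 of their members passed when adjusted over the list alone. Appetite receptors, immediate early genes, neuropeptides and glutamatergic markers had medians, means and tests that differed in sign.

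Within glutamatergic nuclei, Slc17a6 averaged 170 ± 28.7 CPM in the Ucn3-Cre line and 231 ± 23.2 CPM in the vGluT2-Cre line (SD, n = 2 each; log2 fold change -0.42, SE 0.20; adjusted p = 0.999). Spag5, which encodes a spindle-associated protein, averaged 41.2 ± 7.92 and 124 ± 28.1 CPM (log2 fold change -1.56, SE 0.26, adjusted p = 0.999). It was chosen after its values were seen, as 1 of 2 genes called by DESeq2 (adjusted p = 0.00365), the other being a gene model without a name. Spag5 is also among the 10 leading genes of oligodendrocyte cluster 7 over other oligodendrocytes, though not over all other nuclei. Of the nuclei of cluster 7, 89.0% came from vGluT2-Cre replicate 1. In glutamatergic nuclei Spag5 stood at 144 CPM in that library and 105 in vGluT2-Cre replicate 2. In edgeR's quasi-likelihood test 0 of 11073 genes passed, with 286 at an unadjusted p under 0.05. By camera, markers of inhibitory neurons (median log2 fold change -1.11, adjusted p = 4.33e-06), mitochondrial transcripts (median -1.03, adjusted p = 7.19e-06), GABA and glycine receptors (median -0.17, adjusted p = 0.00629) and nuclear genes of oxidative phosphorylation (median -0.15, adjusted p = 0.0085) were lower in the Ucn3-Cre line as sets. Microglial markers were higher (median 0.60, adjusted p = 0.0014). Adjusted over the list alone, 0 members of any fixed list passed, and the other lists did not pass in camera (adjusted p = 0.066 or more). None of these 5 calls held with an estimated correlation (adjusted p = 0.634 for inhibitory and microglial markers and 0.99 for the other lists), a setting with few residual degrees of freedom here. Sub-cluster 6, with Pax2, on the list of inhibitory markers, and Gldc among its leading genes, held 24 of the 189 glutamatergic nuclei of vGluT2-Cre replicate 1 and 4 of 93 of replicate 2. In Ucn3-Cre replicates 1 and 2 it held 8 of 102 and 6 of 158. Medians, means and tests differed in sign for oligodendrocyte, oligodendrocyte precursor and Purkinje cell markers and for sex-linked genes.

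In molecular layer interneurons Grm8, a metabotropic glutamate receptor, was lower in the Ucn3-Cre line (237 ± 85.7 against 643 ± 132 CPM, SD, n = 2 each; log2 fold change -1.58, SE 0.29; adjusted p = 0.0013), the only one of 3687 genes to pass there. In microglia 9 of 7110 genes passed and in oligodendrocyte precursors 4 of 8265, all lower in the Ucn3-Cre line and all listed at 0 in at least 1 library. With only genes counted in every library, edgeR called 0 in microglia (283 at an unadjusted p under 0.05) and 0 in oligodendrocyte precursors (287), and 4 of 5681 in endothelial cells. These were the haemoglobin gene Hbb-bt (724 ± 803 against 95.5 ± 59.4 CPM, SD, n = 2 each; adjusted p = 0.0152), Tmeff2 (57.4 ± 33.8 against 187 ± 4.43; 0.0405), Slc24a2 (71.3 ± 5.05 against 242 ± 164; 0.0381) and Tenm2 (6.78 ± 9.58 against 69.1 ± 32.9; 0.0315). Hbb-bt rested on Ucn3-Cre replicate 2, at 1291 CPM against 156 in replicate 1 and 138 in vGluT2-Cre replicate 1. In edgeR's test 0 genes passed in astrocytes (364 of 11980 at an unadjusted p under 0.05), oligodendrocytes (346 of 11795, and 328 of 11496 without cluster 7), inhibitory neurons (311 of 11135), endothelial cells (148 of 5821) and mural cells (59 of 1773). DESeq2 was not run on these classes.

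The sex comparison set the female libraries against the male ones. Xist, the transcript that silences 1 X chromosome in females (ENSMUSG00000086503, GRCm38 chromosome X, 103460366 to 103483254, minus strand), averaged 3446 ± 186 CPM in the female libraries and was listed at 0 in both male libraries (SD, n = 2). Its antisense partner Tsix averaged 165 ± 41.8 CPM in the female libraries and was listed at 0 in both male ones. The Y-linked genes Eif2s3y and Kdm5d averaged 230 ± 58.5 and 62.8 ± 8.90 CPM in the male libraries and were listed at 0 in both female ones. Uty averaged 173 ± 50.1 CPM in the male and 0.0551 in the female libraries. Ddx3y averaged 104 ± 25.2 CPM in the male libraries and 1.65 ± 2.34 CPM in the female ones, where Ucn3-Cre replicate 1 held all of its counts. The X-linked gene Kdm5c averaged 141 ± 15.7 CPM in the female and 93.0 ± 11.0 in the male libraries (log2 fold change 0.60, SE 0.15, adjusted p = 1.00). Each of the 4 libraries thus had the sex-linked transcripts of the sex that its label gives.

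In edgeR's quasi-likelihood test as planned, 0 of 13795 genes passed between the sexes (458 at an unadjusted p under 0.05; Xist adjusted p = 0.226), while DESeq2 called 203 (175 of them listed at 0 in at least 1 library). Without Ucn3-Cre replicate 2 the planned test called 2, Xist and Malat1. With only genes counted in every library and the sex-linked list, chosen after seeing the data, 5 genes passed: Xist (adjusted p = 0.000109) and Tsix (0.000548) higher in females, and Uty (0.000425), Eif2s3y (0.000548) and Kdm5d (0.000549) lower. That count came to 8 with DESeq2 and to 534 without Ucn3-Cre replicate 2. Over the sex-linked list alone, 7 of 10 genes passed in the planned fit and 9 with genes counted in every library. Mitochondrial transcripts were higher in females as a set (median log2 fold change 0.45, adjusted p = 6.8e-11; 0 of 12 over all genes and 3 adjusted over the list alone), and so were astrocyte markers (median 0.19, adjusted p = 0.0373). The median mitochondrial percent per nucleus did not separate the sexes: it was 0.163 (iodixanol) and 0.303 in the female libraries and 0.255 and 0.254 in the male ones. Neither call held with an estimated correlation (adjusted p = 0.833 for both). The other lists did not pass in camera (adjusted p = 0.055 or more), and apart from sex-linked genes 0 of their members passed when adjusted over the list alone. The haemoglobin, appetite receptor, immediate early, sex-linked, granule cell, microglial and Purkinje cell lists had medians, means and tests that differed in sign. Slc17a6 averaged 38.8 ± 16.1 and 49.2 ± 6.49 CPM in females and males (log2 fold change -0.33, SE 0.34, adjusted p = 1.00).

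Glutamatergic and inhibitory neurons of the same libraries differed in their receptors for appetite signals. Crhr1, a receptor for corticotropin-releasing hormone and urocortin (ENSMUSG00000018634, GRCm38 chromosome 11, 104132855 to 104175523, plus strand), was higher in glutamatergic neurons (72.4 ± 12.7 against 18.8 ± 8.88 CPM, SD, n = 4; log2 fold change 1.89, SE 0.15; adjusted p = 3.66e-10; log2 fold change 2.88 at Leiden resolution 2). Htr2c, a serotonin receptor (ENSMUSG00000041380, GRCm38 chromosome X, 146962513 to 147197277, plus strand), was higher by 1.91 on the log2 scale (504 ± 66.1 against 132 ± 18.2 CPM), and Nmur2, a receptor for neuromedin U, by 3.38 (8.87 ± 1.97 against 0.678 ± 0.541 CPM; 2.59 with called doublets kept). Lepr, the leptin receptor (ENSMUSG00000057722, GRCm38 chromosome 4, 101717404 to 101815352, plus strand), was lower (7.56 ± 2.92 against 19.6 ± 7.60 CPM; log2 fold change -1.26, SE 0.25; adjusted p = 0.000309). Also lower were the cannabinoid receptor Cnr1 (log2 fold change -2.51), the neurotensin receptor Ntsr2 (-1.69) and Ramp3 (-5.00, and -5.77 at Leiden resolution 2), which modifies receptors of the calcitonin family. Of 15 list members tested 4 rose and 6 fell, 11 adjusted over the list alone. All 5 neuropeptide and granin genes that passed among 10 tested were lower in glutamatergic neurons (5 adjusted over the list alone). Nts fell by 2.30, Scg2 by 1.25 and Vgf by 0.95 on the log2 scale, and Scg3 and Scg5 by 0.42 and 0.38. At Leiden resolution 2, Nts came to -5.38 and Vgf to -2.96. As a set this list was lower in camera (adjusted p = 0.00494), but not with an estimated correlation (adjusted p = 0.586). Each named gene had the same direction in 4 of 4 libraries, which the rule for naming required of all but Crhr1 and Lepr.

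Receptors for fast transmitters and ion channels differed in both directions. Among glutamate receptors 8 rose and 13 fell of 22 tested (21 adjusted over the list alone). Grm8 was higher (502 ± 78.1 against 38.4 ± 4.10 CPM; log2 fold change 3.71, SE 0.10), with the NMDA receptor subunit Grin2a (1.98) and the kainate receptor subunit Grik1 (1.71). Grm3 was lower (103 ± 44.8 against 619 ± 38.4 CPM; log2 fold change -2.62, SE 0.13), with Grik3 (-2.34) and Grin2c (-2.01). At Leiden resolution 2, Grm3 came to -3.72 and Grik3 to -3.76. Grm3 also came to -3.56 with the nuclei of the deposited vglut2 table and to -3.45 without sub-clusters 2 and 6. Among GABA and glycine receptors 7 rose and 4 fell of 17 (11 adjusted over the list alone). Gabra2 was higher (167 ± 25.7 against 11.9 ± 4.25 CPM; log2 fold change 3.86, SE 0.14), with Gabrg1 (3.02), the glycine receptor Glra1 (2.41), Gabra5 (1.41, a call lost with DESeq2 and without the library block) and Gabrb2 (0.96). Gabrd was lower (-2.50). Among voltage-gated channels 15 rose and 11 fell of 35 (27 adjusted over the list alone). The sodium channel subunit Scn4b (1.78) and the T-type calcium channel Cacna1h (1.65) were among those higher. The potassium channels Kcnn3 (-1.68) and Kcnq5 (-1.56) and the calcium channel Cacna1e (-1.59) were among those lower. At Leiden resolution 2 these 3 came to -5.06, -3.28 and -2.43, and Kcnn3 to -2.45 with the nuclei of the deposited vglut2 table. In camera glutamate receptors (adjusted p = 0.638), GABA and glycine receptors (0.0827), voltage-gated channels (0.712) and appetite receptors (0.638) did not pass as sets.

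**Figure D2:**
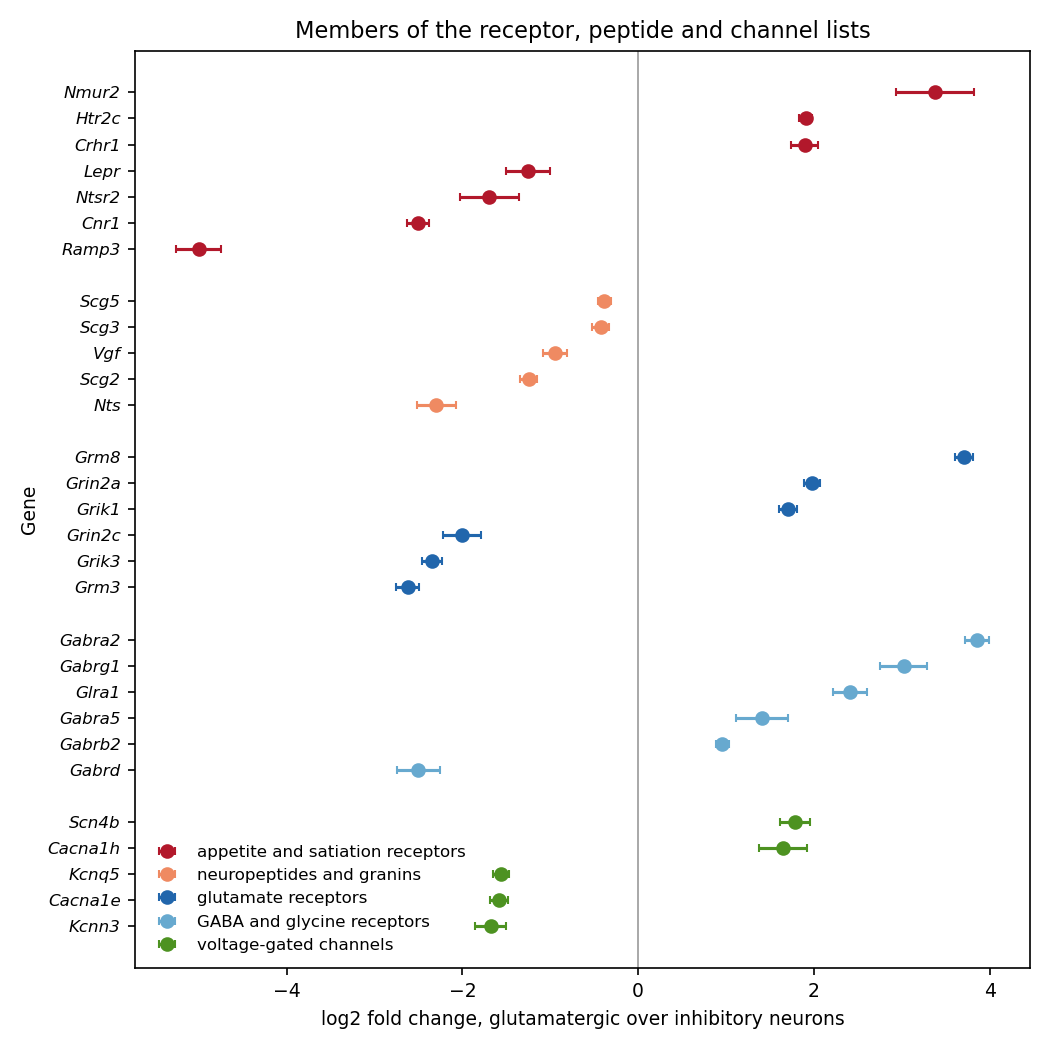
Log2 fold change of glutamatergic over inhibitory neurons (horizontal axis, points, with the standard error as bars, 4 libraries) for named members of 5 gene lists (rows, coloured by list). Values run from -5.00 for Ramp3 to 3.86 for Gabra2, and the 5 neuropeptide and granin genes lie below 0.

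Lists other than those of receptors, peptides and channels were compared in the same neurons. Mitochondrial transcripts were lower in glutamatergic nuclei (9 of 9 over all genes and adjusted over the list alone; mt-Nd1 16.1 ± 11.8 against 41.8 ± 18.0 CPM, SD, n = 4; log2 fold change -1.31, SE 0.22), with a camera call (adjusted p = 6.77e-05) that was lost with an estimated correlation (adjusted p = 0.586). The median nucleus had 9574 counts in the glutamatergic cluster against 5138 and 5490 in the inhibitory clusters 10 and 12. These values are shares of counts, so a difference in mitochondrial expression was not separated from one in counts per nucleus. Of 25 nuclear genes of oxidative phosphorylation 2 rose and 6 fell (8 adjusted over the list alone), among them Cox5a (0.36) and Ndufa4 (-0.43). Of 7 heat shock genes 2 rose and 2 fell (5 adjusted over the list alone), with Hsph1 at 0.72 and Hsp90ab1 at -0.40. The median of this list was negative and its mean positive. Of 6 immediate early genes 1 rose and 2 fell (3 adjusted over the list alone), with Jun at -1.02 and Jund at -0.89. Of 10 sex-linked genes 4 fell (4 adjusted over the list alone). The marker sets behaved as the naming of classes requires: glutamatergic markers were higher (adjusted p = 4.27e-25) and markers of inhibitory neurons (1.54e-11) and molecular layer interneurons (7.3e-14) lower. None of these 3 calls held with an estimated correlation (adjusted p = 0.168, 0.19 and 0.168), although these markers were used to name the classes. Markers of astrocytes, Bergmann glia, granule cells, Purkinje cells, microglia, oligodendrocytes and their precursors did not pass (adjusted p = 0.103 or more). For oligodendrocyte precursor markers the median and mean differed in sign. In all, 3521 of 10978 genes passed in edgeR, 1849 higher and 1672 lower, against 1774 with DESeq2 and 1614 without the library as block. Without that block Lepr no longer passed (adjusted p = 0.0673, against 1.55e-05 to 0.0113 under the other alternatives in which it was tested). Nor did Ntsr2 (0.0638), Gabra5 (0.123), mt-Nd1 (0.119), Cox5a (0.0728), Ndufa4 (0.375), Hsph1 (0.0988), Hsp90ab1 (0.521), Jun (0.218) and Jund (0.0955). With DESeq2, Gabra5 (0.0621), mt-Nd1 (0.0791), Cox5a (0.136) and Jun (0.145) did not pass. Without vGluT2-Cre replicate 2, Jun (0.0531) and Cox5a (0.0622) did not, and Cox5a did not at Leiden resolution 2 (0.0516). Under their other alternatives these genes passed with adjusted p of 0.0354 or less.

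Across all classes, Crhr1 was highest in glutamatergic neurons at 70.5 ± 11.6 CPM (SD, n = 4), against 19.6 ± 9.25 in inhibitory neurons, 3.52 in astrocytes and 2.02 in oligodendrocytes. Against all other nuclei, a comparison chosen after seeing the data, its log2 fold change was 3.85 (SE 0.13, adjusted p = 1.19e-10). Lepr was highest in endothelial cells at 45.0 ± 8.86 CPM, with 19.9 ± 7.46 in inhibitory neurons, 7.26 ± 2.84 in glutamatergic neurons and 0.357 in astrocytes, and its log2 fold change in glutamatergic neurons against all other nuclei was 0.63 (SE 0.30, adjusted p = 0.0831). Slc17a6, a marker used for naming, stood at 201 ± 42.6 CPM in glutamatergic neurons, 30.3 in oligodendrocytes and 39.4 in endothelial cells, which should lack it. Glp1r, the receptor for glucagon-like peptide (ENSMUSG00000024027, GRCm38 chromosome 17, 30901817 to 30940791, plus strand), had 7 counts in all, in 5 of 309 inhibitory nuclei of Ucn3-Cre replicate 2 (1.62%, 95% exact interval 0.527 to 3.74%; median 4607 counts per nucleus). In the same library 0 of 1527 astrocytes (median 2358 counts per nucleus) and 0 of 158 glutamatergic nuclei (median 9729 counts per nucleus) had a count. For the glutamatergic nuclei this allows a share of up to 1.90% with a count, so a difference between the neuron classes was not detectable at this depth. In every other library Glp1r was listed at 0, which too few counts or removal of the gene before deposit would both give.

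The class named glutamatergic fell into 7 sub-clusters, and receptors and channels differed among them. Sub-cluster 6 (42 nuclei, 0 in the deposited vglut2 table) had the markers of another class, so part of these differences is between classes. Slc17a6 stood at 6.63 ± 8.87 CPM there (SD, n = 4), Gad2 at 373 ± 101.4 and Slc6a5 at 221 ± 38.5, against 17.2, 452 and 88.5 in inhibitory neurons. Sub-cluster 7 had both Slc17a6 (134 ± 100 CPM) and Gad2 (220 ± 124), with Gad1 at 170 ± 69.9 CPM and no Meis2 counts. Sub-clusters 2, 4 and 6 had 2, 1 and 2 markers of other classes and 0 glutamatergic markers among their 10 leading genes, and stay unnamed. Sub-cluster 1, with Maf and Kitl among its leading genes, had the highest Crhr1 (144 ± 15.4 CPM, SD, n = 4, against a mean of 29.4 over the other sub-clusters; adjusted p = 7.56e-11). Sub-cluster 3, with Kynu, Igf1 and Pde1a among its leading genes, had the highest Htr2c (1028 ± 130 against 386 CPM; adjusted p = 5.13e-13), and also the highest Kcnq5 (488 ± 96.6 against 178 CPM), Cacna1g and Scg2. Cacna1e stood at 235 ± 73.5 CPM there and at 218 ± 13.9 in sub-cluster 7. Sub-cluster 5 had the highest Kcnc2, a fast potassium channel (609 ± 129 against 252 CPM; adjusted p = 1.2e-12). Sub-cluster 7 had the highest Cnr1 (79.6 ± 28.2 against 20.9 CPM, SD, n = 3), Vgf, Gabrb1 and Glra1. Of these, Cnr1 and Vgf were also higher in inhibitory than in glutamatergic neurons, and Glra1 was lower, so part may be a difference between classes. Sub-cluster 6, with its inhibitory markers, had the highest Hcrtr2, an orexin receptor (234 ± 37.9 against 33.9 CPM, SD, n = 3), Kcnn3 (191 ± 4.72 against 15.7 CPM), Grm3, Grm7, Grik3 and Gabrg3. All of these but Gabrg3 were also higher in inhibitory than in glutamatergic neurons (Hcrtr2 log2 fold change -0.62, Grm7 -1.24). Sub-cluster 2, with the oligodendrocyte genes St18 and Aspa among its leading genes, had the highest Adipor2, an adiponectin receptor, and Kcna1. Lepr had too few counts for the test, with 23.4 ± 32.6 CPM in sub-cluster 7 and 21.5 ± 7.67 in sub-cluster 3, and Glp1r had none.

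By list, the F test of edgeR passed 6 of 8 appetite receptors (7 adjusted over the list alone), 5 of 7 neuropeptides and granins (6), 19 of 21 glutamate receptors (21), 10 of 14 GABA and glycine receptors (10) and 25 of 32 voltage-gated channels (25), 65 genes of these 5 lists. It also passed 1 of 1 immediate early gene (1 adjusted over the list alone), 1 of 6 heat shock genes (0), 4 of 5 mitochondrial transcripts (4), 2 of 20 nuclear genes of oxidative phosphorylation (0) and 1 of 9 sex-linked genes (1). Over all genes 1669 of 6099 passed, against 401 of 4662 at Leiden resolution 2, where 25 list members passed, and 1039 of 5115 without vGluT2-Cre replicate 1. At Leiden resolution 2 the class held only 29 to 61 nuclei per library, against 93 to 189 in the main setting. Without sub-clusters 2 and 6, 50 list members passed, Crhr1, Htr2c and Kcnc2 among them (adjusted p = 3.7e-09, 2.96e-12 and 4.86e-11), and Grin2b did not (adjusted p = 0.135). Sub-cluster 7, with markers of both classes, was kept in that alternative.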

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

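The differences given here were picked out after the values were seen, and none of them was tested. They stand out because the difference between the lines had opposite signs in the 2 sexes, with 1 library per line and sex. The share of glutamatergic nuclei in the Ucn3-Cre line minus that in the vGluT2-Cre line was 0.514 percentage points between the female libraries and -0.976 between the male libraries. For Slc17a6 in all nuclei, the log2 ratio of the Ucn3-Cre over the vGluT2-Cre library was -0.85 in females and 0.26 in males. Within glutamatergic nuclei its sign did not turn: it stood at 150 against 248 CPM in females and at 190 against 215 in males. Over all nuclei its mean of 44.2 CPM was not far above that of glia, which should lack it (22.0 in astrocytes to 40.5 in microglia). The level in all nuclei is therefore not that of the neurons alone. The female Ucn3-Cre library is also the one made by iodixanol gradient, so sex, extraction and differences between single libraries are not separated, and whether the lines differ between the sexes was not tested.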

How the results depend on the processing

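The fits with at least 1000 genes per nucleus, those without sub-clusters 2 and 6 or 6 alone, those of genes counted in every library, the share of oligodendrocytes with cluster 4 and the comparison with all other nuclei were chosen after seeing the data. The share of glutamatergic nuclei by line had no call to lose. Its difference of -0.23 percentage points reversed to 0.447 with at least 1000 genes per nucleus, ranged from -1.01 to 0.549 when single libraries were left out (0.549 without vGluT2-Cre replicate 1), and came to -0.11 without sub-cluster 6 and -0.003 at Leiden resolution 2. At that resolution the class was smaller, with mean shares of 0.839% in the Ucn3-Cre line and 0.842% in the vGluT2-Cre line. In edgeR 0 genes passed between the lines, in all nuclei and in glutamatergic nuclei, under each alternative to the planned fit run in edgeR, that of genes counted in every library included, and without each library (0 to 0 in both). DESeq2 called 238 and 2, and the replicate number as a block left 178 and 332 genes at an unadjusted p under 0.05. The replicate 2 libraries also share a tag in their column names, of unstated meaning, and had the highest correlation of any pair (0.993). Deviations of libraries of the same number had a correlation of 0.157 over 11406 genes. Between the sexes DESeq2 called 203 genes, the fit without single libraries 0 to 2 (2 without Ucn3-Cre replicate 2), and the fit of genes counted in every library 5. In that fit the line comparison went from 0 to 6 with DESeq2 and ranged from 0 to 189 without single libraries (2 without vGluT2-Cre replicate 1, 189 without replicate 2), and the sex comparison went from 5 to 8 with DESeq2 and ranged from 6 to 534 (534 without Ucn3-Cre replicate 2). The cause of these counts was not tested, but without a library the lone sample of a group is assumed to vary like the others.

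The 73 list members past the threshold between glutamatergic and inhibitory neurons ranged from 70 to 75 without single libraries and from 50 (no library block) to 81 (no low-count filter) otherwise. The 65 across sub-clusters ranged from 51 to 64 without single libraries and fell to 25 at Leiden resolution 2. There the class held only 29 to 61 nuclei per library, against 93 to 189 in the main setting. How much of the fall this explains was not tested. With an estimated correlation the lists past camera's threshold went from 5 to 0 between the lines in all nuclei, from 5 to 0 in glutamatergic nuclei, from 2 to 0 between the sexes and from 5 to 0 between glutamatergic and inhibitory neurons. That setting has few residual degrees of freedom, so these losses do not decide whether the calls were right. Nor do the p-values with the preset correlation, which are too small where list members move together. With genes counted in every library the lists past the threshold came to 8 for the lines in all nuclei and 5 for the sexes. Among named genes, Hspa8 reversed between glutamatergic and inhibitory neurons to 0.0777 on the log2 scale at Leiden resolution 2 (adjusted p = 0.585, against 0.0199 to 0.802 over its alternatives). Slc17a6, with no call to lose between the lines in all nuclei, ranged from -0.79 (without Ucn3-Cre replicate 2) to 0.19 (without Ucn3-Cre replicate 1). Other named genes kept their direction between glutamatergic and inhibitory neurons, 687 combinations of gene and alternative keeping their side of the threshold and 46, of 16 genes, losing the call. Among genes that kept their call, those that moved by over 1.5 times at Leiden resolution 2 included Crhr1 (2.88), Ramp3 (-5.77), Nts (-5.38), Vgf (-2.96), Grik3 (-3.76), Grm3 (-3.72), Kcnn3 (-5.06), Kcnq5 (-3.28) and Cacna1e (-2.43); with called doublets kept Nmur2 did (2.59). The moves at Leiden resolution 2 are those of the smaller class, and their cause was not tested further. The planned comparisons of Ucn3 were not run. In simulated data the planned line fit of all nuclei called 12% of genes changed 2-fold and 56% of those changed 4-fold. Those data lacked the spread particular to single genes and the genes at 0 in whole libraries, so the real shares may be lower.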

Other observations

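The sex comparison within classes, the levels of YFP by class, the test of expected counts at genes listed at 0, the look at variable genes behind oligodendrocyte cluster 7 the tests of sex and line alone for that cluster and the test for free RNA in sub-cluster 2 were chosen after the result was seen. In endothelial nuclei the haemoglobin genes Hba-a1, Hba-a2 and Hbb-bs were lower in both female than in both male libraries. Hba-a1 averaged 90.4 ± 35.0 and 798 ± 168 CPM (SD, n = 2 each; log2 fold change -3.20, SE 0.30; edgeR adjusted p = 0.000171). Hba-a2 averaged 45.9 ± 7.36 and 576 ± 3.80 CPM (log2 fold change -3.55, SE 0.28; adjusted p = 4.57e-05), and Hbb-bs averaged 528 ± 327 and 4882 ± 2673 CPM (log2 fold change -3.27, SE 0.44; adjusted p = 0.0057). Hbb-bt, which passed only with genes counted in every library (log2 fold change -3.21, adjusted p = 0.00702), did not separate the sexes: it stood at 156 and 53.5 CPM in the female libraries and at 138 and 1291 in the male ones. Haemoglobin is made by red blood cells and their precursors, and how its RNA came into this class was not tested. In this class 8 of 5821 genes passed (12 of 5681 with only genes counted in every library), the others being Xist, Gimap8 and the Y-linked Ddx3y, Eif2s3y and Uty. Gimap8 (72.5 ± 2.84 CPM in females) is listed at 0 in both male libraries, as genes removed before deposit would be, and is not among the 12.

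YFP counts were found in glia as well as neurons. They averaged 42.5 ± 6.77 CPM in astrocytes of the Ucn3-Cre line and 121 ± 0.209 in those of the vGluT2-Cre line (SD, n = 2 each), 72.6 ± 29.1 and 92.3 ± 25.6 in endothelial cells, 16.0 ± 2.10 and 44.3 ± 10.3 in glutamatergic neurons, 12.9 ± 4.78 and 31.5 ± 0.525 in inhibitory neurons, and 4.33 ± 2.90 and 28.2 ± 7.58 in oligodendrocytes. No class-specific cause of these levels was tested.

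A first pattern is that 4186 genes are listed at 0 in at least 1 library. Too few counts are argued against: in each library at least 656 genes at 0 have an expected count of 20 or more from their share in the other 3 libraries, up to 577 for Amt in vGluT2-Cre replicate 2. A difference between the lines is argued against too, since genes at 0 in both libraries of 1 line were 1.09 times as many as in the other pairs of libraries. Removal of genes per library before deposit is consistent with the values: where 20 to 100 counts were expected, genes at exactly 0 outnumber those with 1 to 5 counts by at least 310 to 1 in each library. Which step removed them, and by what rule, stays open.

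Another pattern is oligodendrocyte cluster 7, of which 1115 of 1253 nuclei (89.0%) came from vGluT2-Cre replicate 1, where it made up 20.7% of nuclei against 0.449 to 2.08% elsewhere, while clusters 3 and 4 made up 2.17 and 2.38% there against 12.8 to 17.2% and 10.1 to 12.7%. Genes listed at 0 did not enter the clustering (0% of the 2000 variable genes), so they are not its direct source. The choice of variable genes ranks a gene at 0 in a library last there, which largely fixed this share in advance. Effects of the step behind the zeros on other genes were not tested. A shift of that whole library in all cell types stays open. The 50 leading genes of the cluster over other oligodendrocytes were compared between that library and the others. Their median log2 ratio was 0.47 in astrocytes, where 48 of 50 were higher, and 0.23 in inhibitory neurons, with quartiles of -0.08 and 0.59. The 50 include the Y-linked Ddx3y, Uty and Eif2s3y. These differ by sex, since that library is male and both female libraries are among the others. Sex does not cover all of their difference. In sums over all nuclei that library also stood above the other male library, with Ddx3y at 121 against 85.7 CPM. Uty stood at 209 against 138 CPM and Eif2s3y at 271.5 against 189. For a glucocorticoid or time-of-day response, the medians of the 2 lists lie at percentiles 27.8 and 72.0 of random lists. Both are within the range set beforehand as counting against it. The members of each list go both ways, so a median cannot decide, and this response stays open as well. Sex alone and line alone are argued against by the shares of the other male library (0.449%) and the other vGluT2-Cre library (0.503%), while the age of 2 months, held by that library alone, and combinations of line, sex and age stay open and untested.

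The last pattern is glutamatergic sub-cluster 2, whose leading genes include the oligodendrocyte genes St18 and Aspa. Whole doublets with oligodendrocytes are argued against for the typical nucleus: the median was 2.67 counts of oligodendrocyte markers, against 50.1 in oligodendrocytes, a ratio of 0.0533. A median does not speak to a minority of nuclei, so doublets among those stay open. Of its 105 nuclei, 80 were in the deposited vglut2 table. Free RNA shared by all droplets stays open: the share of these markers was at least 2.51 times that in the other 6 sub-clusters in each library, short of the 3 times set as the bound, and 3.45 times with sub-cluster 6 left out, which itself held 0.0633% against 0.0999% in sub-cluster 2 (0.174 against 0.0615% in Ucn3-Cre replicate 1). The astrocyte markers had 0.549 to 0.822 times the share of the other 6. Fragments of oligodendrocytes attached to neuronal nuclei were not tested, nor was a biological explanation, for which the design has no group.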
